A study of Mus musculus with 4 samples.

How the data were processed

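Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on pools of 30 to 40 cochleae from wild-type mice of 4 to 5 weeks, with an antibody to the transcription factor SIX1, an antibody to H3K27ac (an acetylated histone that marks active promoters and enhancers) or IgG. Single-nucleus RNA sequencing (snRNA-seq) was done on cochlear nuclei of control mice and of littermates with a conditional deletion of Six1 (cKO), collected 2 weeks after tamoxifen per the labels. The nuclei came as 4 barcoded samples, 3 controls and 1 labelled cKO, which were pooled before sequencing. They were barcoded by splitting and pooling over wells, so that a nucleus is known by its combination of wells. The labels do not say whether a barcoded sample is 1 animal or several, nor how the 3 controls differ. The p-values of the gene and list tests therefore rest on the spread between these samples, pooled in part over genes, which may be technical.

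The deposited matrix holds raw counts of transcripts (UMIs) per barcode and gene, whole numbers that the authors did not normalize. Its 110592 barcodes are every combination of 12 first-round, 96 second-round and 96 third-round wells, so the deposited counts had not been reduced to nuclei. GRCm38 and Seurat are named for the snRNA-seq per the submitters' processing notes, with no role or version for Seurat. The 2 peak files hold coordinates alone, in mm10, with no score, height or p; FastQC 0.11.2, HISAT2, MACS2 2.1.1 and bedtools are named for them per the submitters' processing notes. Whether a peak list came from pooled or intersected samples is not given in the sources used here. The IgG sample has no peak list here and was not used.

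Barcodes with at least 300 genes and at most 10% mitochondrial counts were taken as nuclei, which left 37364. The summed counts over all barcodes were 11949462, 13705259 and 14356889 in the 3 controls and 22233961 in the library labelled cKO. The nuclei numbered 5624, 7914 and 8242 in the controls and 15584 in the library labelled cKO, with median UMIs of 796, 651, 737 and 614. Scrublet marked 3 of 37367 barcodes as doublets (0.00803%), a share so low that the caller did not work, so doublets remain in the data. RNA that leaks in a well reaches every barcode of that well. Each nucleus was therefore also compared with the median UMIs of the 96 barcodes that shared its first-round and second-round wells. The share of nuclei under 3 times that median was 70.6%, 77.2% and 75.2% in the controls and 85.4% in the library labelled cKO.

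No deposited annotation of cell types was used here. Nuclei were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 30 principal components and 15 neighbours at Leiden resolution 1.0, without integration, which gave 25 clusters. Marker lists for each class were fixed before the data were examined, as were the nucleus filters, the tests, the 22 gene lists and the alternatives. The naming rule was set after the clusters had been seen. A cluster was named after a class when at least 3 of its markers stood among the cluster's 60 leading genes by fold, at least 1.5 times as many as for any other class. No other class could have more markers among the cluster's 10 leading genes. A cluster with far fewer UMIs than its samples and none of its markers among those 10 was also left unnamed. Cluster 2, with 4 spiral ganglion neuron markers against 1 of oligodendrocytes, stayed unnamed because only the latter stood among its 10 leading genes. By these rules 15 clusters received a name and 10 did not. A class rebuilt in this way may differ from the authors' own classes.

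Raw counts were summed per barcoded sample and class and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, 2-sided, Benjamini-Hochberg adjustment at 0.05). The spread came from the 3 controls alone (2 residual degrees of freedom), and the lone cKO sample was assumed to vary like them. edgeR also drew each gene's spread towards that of all genes, with a weight given as prior degrees of freedom. This was 6.31 over all nuclei, 62.4 in supporting cell-like nuclei and 71.9 in Schwann or satellite glia-like nuclei. In spindle or root cell-like nuclei it was infinite, so a gene's own spread between controls had no weight there. A class was tested when each barcoded sample held at least 20 nuclei of it. DESeq2 1.42.0 and limma voom (limma 3.58.1) were the other tools. Adjusted p-values come from edgeR unless another tool is named. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a class. Levels are given as CPM, counts scaled to the total of each sample and computed here from the deposited counts, as mean ± SD of the 3 controls against the single value of the library labelled cKO. Intervals for sums of counts are exact Poisson intervals and those for shares exact binomial ones, both at 95% and for counting error alone. A count of 0 was read against a floor of 3 counts.

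The text names Six1 and, in each main comparison, up to 10 genes with the largest rise and 10 with the largest fall among called genes whose level in the library labelled cKO lay outside the control range. Genes with names of the form Gm or Rik and Y-linked, Xist and mitochondrial genes are counted only, apart from members of a fixed list. Uty, Xist, D430041D05Rik and the genes named in the other classes, outside the fixed lists, fall outside this rule and were chosen after their values were seen. From each list the called members are named, or up to 2 members with the largest change as values. Where a comparison had fewer than 5 calls, the 10 genes with the smallest p are given as values. Nearest SIX1 peaks are given for 10 genes fixed in the same way.

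SIX1 peaks were compared with H3K27ac peaks by overlap of at least 1 bp, and with gene spans of the RefSeq annotation of GRCm38.p6, against 100 random placements of the same peaks on the same chromosomes. The gene table gives no strand, so distances are to a gene's span or to either of its ends. It held a place for 70.5% of the matrix's genes, matched by symbol or synonym. Distance to start sites and the SIX1 motif in the peaks were planned but not run, since no strand and no genome sequence was used here.

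The tests were tried on simulated counts drawn from the real means, with 200 genes changed by known factors in 5 runs each. In the supporting cell-like comparison (7891 genes) 29.3% of genes changed 2-fold, 76.4% of those changed 4-fold and 86.4% of those changed 8-fold were found, with 4.8 false calls among 140 calls per run on average. Over all nuclei (16942 genes) the shares were 43.6%, 85.7% and 93.0%, with 5.6 false calls among 162. These false calls are those of the simulated counts and give no error rate for the calls in the real data. Each simulated gene took the spread typical of its level and had none of its own. The shares found may therefore be higher than in the real data. In real supporting cell-like counts, each control set apart in turn called 2, 9 and 11 genes, against 13 for the library labelled cKO. The alternatives varied the normalization, the test, the filter on low counts, the nucleus filter, doublets, the number of nuclei, the Leiden resolution, each control sample, the overlap and distance of peaks and the correlation in camera. Further ones chosen after seeing the data were a robust dispersion, 1000 UMIs per nucleus, nuclei above 3 times the median of their pair of wells, each well of the library labelled cKO left out, each supporting cell-like cluster left out, genes of like length and SIX1 peaks with H3K27ac.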

Results

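The series addressed what SIX1, a homeodomain transcription factor of inner ear development, does in the adult cochlear sensory epithelium. Nuclei of whole cochleae were profiled from 3 control samples and 1 sample labelled cKO, and SIX1 and H3K27ac peaks were mapped in wild-type cochleae. Between 7885610 and 19352408 counts per barcoded sample fell in nuclei. The nuclei gave classes of the sensory epithelium (supporting cell-like, with 110, 302 and 174 nuclei in the controls and 232 in the library labelled cKO, and hair cell-like, with 11, 18 and 20 against 10), of the lateral wall (spiral ligament fibrocyte-like, strial marginal and intermediate cell-like, spindle or root cell-like), Reissner membrane-like and endothelial cell-like nuclei, spiral ganglion neuron-like nuclei and Schwann or satellite glia-like nuclei.

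Six1 did not pass as lower in the library labelled cKO in any class. Over all nuclei it stood at 44.5, 72.7 and 65.2 CPM in the controls and 64.7 CPM in the library labelled cKO, a log2 change of 0.02 (SE 0.23, adjusted p = 0.9997). In supporting cell-like nuclei it stood at 76.2, 136 and 151 CPM in the controls and 109 CPM in the library labelled cKO, a log2 change of -0.23 (SE 0.29, adjusted p = 0.998). Hair cell-like nuclei held 5, 5 and 16 Six1 counts in the controls and 3 in the library labelled cKO, or 150 CPM (98.2 to 220) in the pooled controls against 77.1 CPM (15.9 to 225). Six1 passed the test in none of the 10 comparisons run with edgeR (unadjusted p from 0.0781 in Schwann or satellite glia-like nuclei to 0.983 in strial intermediate cell-like nuclei), and its level over all nuclei lay between those of the controls in each of the 3 wells of the library labelled cKO (62.8 to 68.8 CPM, against 40.6 to 81.4 CPM in control wells). The sources used here do not say which part of Six1 the deletion removes, so counts over the whole gene may not check the label, and every direction given here is that of the library labelled cKO. Without control replicate 1 the log2 change over all nuclei was -0.14. Six1 lay below every control, without passing, in Schwann or satellite glia-like nuclei (24.9 CPM against 39.7, 27.3 and 47.1 CPM, log2 change -0.77), in supporting cell-like nuclei at 500 genes per nucleus (70.4 CPM against 85.4, 97.9 and 119 CPM, -0.52) and in their cluster 20 alone (60.5 CPM against 77.5, 90.1 and 124 CPM, -0.67).

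In supporting cell-like nuclei, Nrxn3, a synaptic adhesion gene of the neurexin family, was higher in the library labelled cKO than in the controls. It reached 1026 CPM against 318 ± 31.7 CPM (SD, n = 3), a log2 change of 1.65 (SE 0.21, adjusted p = 3.89e-07). Single wells varied far more: Nrxn3 ran from 83.2 to 669 CPM in control wells, both ends in control 1. In the library labelled cKO it ran from 647 to 1360 CPM, and 2 wells lay above every control well. Nrxn3 also had a positive log2 change, of 0.74, in all other nuclei summed. Tecta, which encodes alpha-tectorin of the tectorial membrane, rose by a log2 change of 1.98 (SE 0.35, adjusted p = 0.000529) to 163 CPM from 36.2 ± 30.1 CPM. Klhl14, a Kelch-like adaptor gene, rose to 351 CPM from 154 ± 71.7 CPM (log2 change 1.26), Cpne8, a copine gene, to 283 CPM from 123 ± 24.5 CPM (1.16), and Lctl, a Klotho family gene, to 109 CPM from 42.7 ± 2.77 CPM (1.33; adjusted p = 0.0142, 0.0115 and 0.0483). Lctl was also called higher in Schwann or satellite glia-like nuclei (106 CPM against 43.5 ± 21.3 CPM, log2 change 1.25). Ribosomal RNAs of the mitochondrial genome fell, mt-Rnr1 to 335 CPM from 915 ± 108 CPM and mt-Rnr2 to 541 CPM from 1395 ± 104 CPM. Mitochondrial genome transcripts lay lower in all 10 comparisons. Over all barcodes they were 0.258% of counts in the library labelled cKO, against 0.429% to 0.768% in controls. Their fall is therefore not particular to supporting cell-like nuclei.

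In all, 13 of 8386 genes passed edgeR's test in supporting cell-like nuclei, 8 higher and 5 lower. Leaving out any 1 control raised that number. 363 genes had an unadjusted p under 0.05, fewer than the 419 expected by chance, DESeq2 called 4 genes and limma voom 10. Among the nuclei of the same clusters above the background of their wells 19 genes passed, 11 of them among the 13, with Nrxn3 at a log2 change of 1.37 (adjusted p = 4.26e-06) and Tecta at 1.98 (adjusted p = 1.09e-06). The number of calls varied with the nuclei counted: 0 genes passed edgeR at 500 genes per nucleus (182 at an unadjusted p under 0.05) and 0 when nuclei above the background were clustered anew (215). Nrxn3 had a log2 change of 1.53 (SE 0.31, adjusted p = 0.519) at 500 genes and a smaller one of 0.94 (SE 0.30, adjusted p = 0.610) when clustered anew. The remaining calls were Gtdc1 (log2 change 1.13), Nox3 (5.28), an uncharacterised Rik gene and 3 Y-linked genes that were lower. Gtdc1 lost its change without 1 well of the library labelled cKO (log2 change 0.15, adjusted p = 0.999), and Klhl14, Cpne8, Lctl and Tecta kept positive log2 changes of 0.90, 0.68, 1.09 and 1.49 there but no longer passed (adjusted p from 0.669 to 0.999). Nrxn3 passed without that well too (log2 change 1.27, adjusted p = 0.00464). Nox3, an NADPH oxidase gene of the inner ear, had 25 counts in the library labelled cKO, 14 of them in 1 nucleus, and 1 of 586 control nuclei had a count. Its 0.423 ± 0.733 CPM in controls lay under the floor of 3 counts in each of them.

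The supporting cell-like class joined 3 clusters. Cluster 13, led by Epyc, Ceacam16 and Otoa, held 64, 217 and 114 nuclei of the controls and 138 of the library labelled cKO. Cluster 20, led by Dgkb and Klhl14 with Fgfr3 and Jag1, held 37, 64 and 59 against 61. Cluster 23, led by Tecta with Otogl and Otog, held 9, 21 and 1 against 33. Of the Nrxn3 counts in the library labelled cKO 85.2% lay in cluster 20, where Nrxn3 rose by a log2 change of 1.98 (SE 0.29, adjusted p = 0.0142), and 97.1% of Klhl14 counts lay there too. Without cluster 20 neither gene passed (Nrxn3 0.66, adjusted p = 0.650; Klhl14 -0.17, adjusted p = 0.9998), and Cpne8 did not either (0.46, adjusted p = 0.9998). Without cluster 23 Tecta stood at 17.7 CPM in the library labelled cKO against 14.4, 14.8 and 2.71 CPM in the controls. Tecta and Klhl14 are themselves among the leading genes of clusters 23 and 20, so their levels were part of the clustering.

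Nrxn3 lies on chromosome 12 from 88722701 to 90334935 (mm10) and holds 1 SIX1 peak, at 88813545 to 88813648. Lctl, on chromosome 9 from 64117123 to 64138118, also holds 1, at 64125451 to 64125598. Neither gene had a SIX1 peak overlapping H3K27ac within 5 kb. Nrxn3 spans 1612 kb, and long genes meet peaks more often. Among protein-coding genes with at least 100 counts, those near a SIX1 peak had a median span of 55.1 kb, against 26.9 kb for the others. A peak inside Nrxn3 therefore does not by itself mark it as bound and regulated by SIX1. Tecta (chromosome 9, 42329622 to 42401690), Klhl14 (chromosome 18, 21550379 to 21672929), Cpne8 (chromosome 15, 90487481 to 90679388), Gtdc1 (chromosome 2, 44564412 to 44927717) and Nox3 (chromosome 17, 3635240 to 3696261) had no SIX1 peak within 5 kb.

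**Figure D1:**
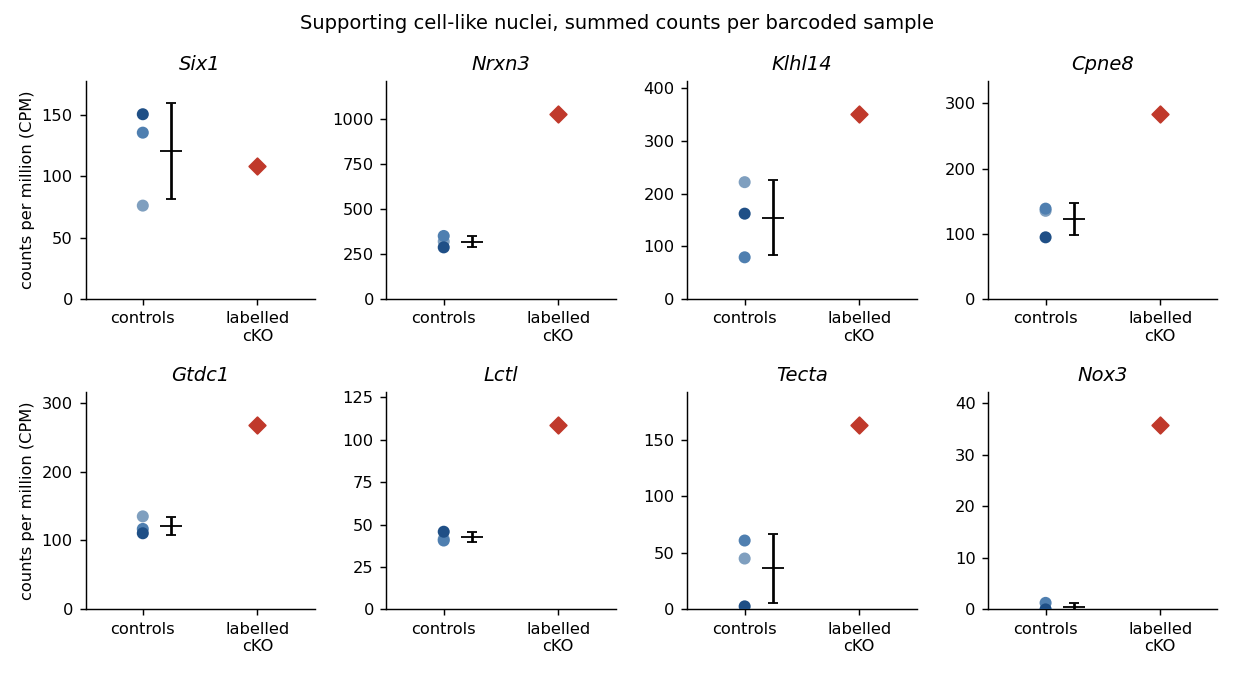
CPM (y axis, from 0) of Six1 and of the 7 genes named as higher in supporting cell-like nuclei, for the 3 control samples (circles, with mean and SD beside them) and the library labelled cKO (diamond). Six1 in the library labelled cKO (109 CPM) lies among the controls, and the other 7 genes lie above all 3 controls.

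No list of developmental genes passed in supporting cell-like nuclei. Of 22 fixed lists 2 passed camera at the preset correlation and none with an estimated one. Mitochondrial genome transcripts were lower (median log2 change -0.89; 2 of 7 measured members fell and 5 did not pass, the same when adjusted over the list alone; adjusted p = 3.23e-08; adjusted p = 0.545 with an estimated correlation). Gap junction and potassium recycling genes, which serve the return of potassium to the endolymph, lay higher as a list (median log2 change 0.21, positive in 14 of 17 measured members; adjusted p = 0.0420; adjusted p = 0.822 with an estimated correlation). That list did not pass without control 2 (adjusted p = 0.596) or control 3 (adjusted p = 0.174). No member of that list passed, also when adjusted over the list alone. Among them Clcnka stood at 24.3 CPM against 9.83 ± 5.94 CPM and Atp1b2 at 84.5 CPM against 57.9 ± 14.2 CPM.

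None of the 16 measured supporting cell identity genes passed, over all genes or adjusted over the list alone. Lgr6 stood at 2.86 CPM, under the floor of 3 counts, against 19.6 ± 2.72 CPM, and Slc1a3 at 198 CPM against 311 ± 102 CPM (camera adjusted p = 0.630). None of the 13 measured genes of the PAX-SIX-EYA-DACH network, in which SIX1 acts with EYA cofactors, passed, with Eya2 at 203 CPM against 135 ± 45.5 CPM and Sall1 at 40.1 CPM against 18.0 ± 3.22 CPM (camera adjusted p = 0.312). In the list of tectorial and otic matrix genes Tecta was the 1 member of 16 that passed, over all genes and adjusted over the list alone (camera adjusted p = 0.630, higher, against a median of -0.03 and a mean of -0.04). Notch (9 measured), Wnt (25) and FGF (13) signalling genes had no call, with Jag1 at 119 CPM against 86.9 ± 21.9 CPM, Lef1 at 28.6 CPM against 61.5 ± 21.9 CPM and Fgf10 at 15.7 CPM against 29.4 ± 5.03 CPM. TGF-beta and BMP genes (20 measured) also had none, with Bmp4 at 7.16 CPM against 24.1 ± 10.2 CPM. Camera gave these 4 lists adjusted p-values of 0.998, 0.630, 0.786 and 0.580, and the Wnt list had a median of 0.01 but a mean of -0.18 and a lower direction. Hair cell transcription factors (4 measured), mechanotransduction genes (18) and hair cell synapse genes (12) had no call either (camera adjusted p = 0.998, 0.630 and 0.749). None of these 7 lists had a member that passed when adjusted over the list alone. The transcription factors (median 0.04, mean 0.01) and the synapse genes (median 0.03, mean -0.61) both had a lower direction in camera. Hair cell genes were few and low here: Slc17a8, the vesicular glutamate transporter of inner hair cells, had no count in the library labelled cKO (floor 4.29 CPM) against 13.2 ± 11.2 CPM in controls, and Myo3b stood at 48.7 CPM against 26.2 ± 10.4 CPM. The lists of p53 and apoptosis (11 measured), unfolded protein response (10), antioxidant (16), immediate early (3), inflammation (8), cell cycle (6), adhesion (21), myelin (10), nuclear oxidative phosphorylation (16) and spiral ganglion neuron genes (21) had no call over all genes or adjusted over the list alone, with camera adjusted p-values between 0.580 and 0.914. The unfolded protein response (median 0.09, mean -0.04) and adhesion (median 0.03, mean -0.06) had a lower direction. Examples were Casp3 at 20.04 CPM against 11.1 ± 2.89 CPM, Hsp90b1 at 80.2 CPM against 147 ± 71.4 CPM and Cdh4 at 40.1 CPM against 77.7 ± 12.1 CPM.

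Hair cell-like nuclei held mechanotransduction and synapse genes in all 4 barcoded samples, but changes in them were not tested. This class, marked by Slc26a5, Slc17a8, Otof, Loxhd1 and Tmc1, held 11, 18 and 20 nuclei in the controls and 10 in the library labelled cKO, fewer in 3 of the 4 samples than the 20 set for a test before the data were seen, so values carry counting intervals that leave out the spread between samples. Among stereocilia genes, Loxhd1 was at 3211 CPM (2673 to 3826) against 1995 CPM (1790 to 2217) in the pooled controls, Tmc1, a subunit of the transduction channel, at 925 CPM (648 to 1280) against 966 CPM (825 to 1124) and Cdh23, a tip link cadherin, at 694 CPM (457 to 1009) against 677 CPM (560 to 811). Among synapse and excitability genes, Otof was at 2492 CPM (2021 to 3040) against 1573 CPM (1392 to 1772), Cacna1d at 4804 CPM (4140 to 5544) against 4592 CPM (4278 to 4923) and Slc17a8 at 796 CPM (541 to 1130) against 839 CPM (708 to 987). Slc26a5, the outer hair cell motor protein prestin, was at 411 CPM (235 to 667) against 434 CPM (341 to 544). Ikzf2, a transcription factor of outer hair cells, was at 206 CPM (88.7 to 405) against 416 CPM (326 to 524), a ratio of 0.494 (0.205 to 1.03). Several of these genes define the cluster, so their presence in it is not a finding.

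Over all nuclei, few genes differed between the library labelled cKO and the controls in the main setting. The number of calls varied widely with the filter on low counts and with the controls used. Zfp335os, a long noncoding RNA antisense to Zfp335 by its name, was the 1 gene of 17425 that passed: 50.6 CPM against 8.52 ± 1.15 CPM (log2 change 2.497, SE 0.18, adjusted p = 0.00814). At an unadjusted p under 0.05 there were 570 genes, fewer than the 871 expected by chance, DESeq2 called 7 and limma voom 1. Its counts lay in 1 of the 3 wells of the library labelled cKO (158 CPM, against 11.7 and 11.3 CPM in the others and 5.21 to 12.9 CPM in control wells), and without that well 0 genes passed (642 had an unadjusted p under 0.05). Gtdc1 (295 CPM against 124 ± 9.43 CPM, adjusted p = 0.111) and Lztfl1 (67.8 CPM against 25.5 ± 1.62 CPM, adjusted p = 0.111) were likewise over 1.5 times the highest control well in 1 well only.

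Gjb2, which encodes connexin 26 of cochlear gap junctions, did not pass over all genes (128 CPM against 60.6 ± 12.3 CPM, log2 change 1.02, SE 0.17, adjusted p = 0.511). It passed when adjusted over its list alone. Every well of the library labelled cKO (115 to 156 CPM) lay above every control well (42.7 to 85.2 CPM). These wells are parts of 1 barcoded sample, so they do not replicate the difference. Gjb2 in supporting cell-like nuclei ran from 76.7 to 125 CPM in wells of the library labelled cKO. The highest control well there stood at 136 CPM, so 0 wells lay above every control well. Other genes among the 10 with the smallest p over all nuclei were the class I histocompatibility gene H2-T22 (0.723 CPM against 8.54 ± 2.89 CPM, adjusted p = 0.310), Pramef12 (3.15 CPM against 0.219 ± 0.107 CPM, under the floor of 3 counts in 2 of the controls, adjusted p = 0.511) and 4 genes with Gm names. Pramef12 was carried by 1 well of the library labelled cKO too (20.5 CPM over all barcodes of that well, against 0.934 CPM in the next well), as were 2 of the 4 Gm genes.

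**Figure D2:**
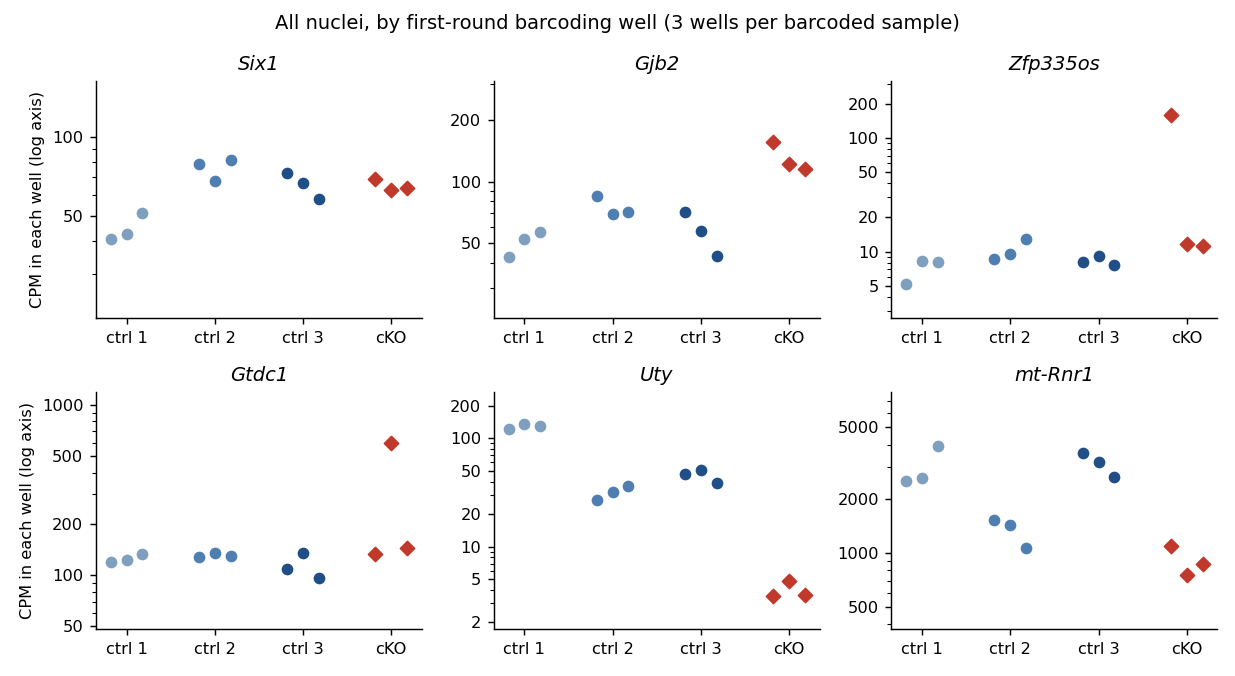
CPM over all nuclei (y axis, log scale) in each of the 12 first-round wells, 3 per barcoded sample, for Six1, Gjb2, Zfp335os, Gtdc1, Uty and mt-Rnr1. Zfp335os and Gtdc1 stand out in 1 well each (158 and 597 CPM), while Gjb2 is higher and Uty lower in all 3 wells of the library labelled cKO than in any control well.

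Over all nuclei 7 of the 22 lists passed camera at the preset correlation and 0 with an estimated one. Mechanotransduction and stereocilia genes lay higher (median log2 change 0.37, positive in 24 of 29 measured members; 0 called over all genes and 1 adjusted over the list alone; adjusted p = 6.58e-10; adjusted p = 0.562 with an estimated correlation). Ush2a stood at 56.4 CPM against 20.6 ± 8.72 CPM and Grxcr2 at 1.76 CPM against 0.828 ± 0.103 CPM. Unnamed clusters 5 and 21, both with Xirp2, Loxhd1, Otof and Ptprq among their leading genes, made up 7.22% and 0.898% of nuclei of the library labelled cKO against at most 3.06% and 0.462% in a control. Cluster 5 also had Otog, Tectb and Tecta among its leading genes. Its nuclei were close to the background, with a median of 1.08 times the median UMIs of their pair of wells. Gap junction genes lay higher with Gjb2 (median 0.21, 21 measured; adjusted p = 0.000153; adjusted p = 0.562 with an estimated correlation), although Gja1 stood at 1.55 CPM against 3.33 ± 0.539 CPM. PAX-SIX-EYA-DACH genes lay slightly higher (median 0.10, positive in 14 of 15; adjusted p = 0.0348; adjusted p = 0.562 with an estimated correlation), with Dach2 at 172 CPM against 115 ± 13.8 CPM, and so did hair cell transcription factors (median 0.23, 8 measured; adjusted p = 0.0348; adjusted p = 0.679 with an estimated correlation), with Lhx3 at 2.22 CPM against 0.522 ± 0.507 CPM. Without control 3 neither list passed (adjusted p = 0.156 and 0.236), and the transcription factors did not pass among nuclei above the background of their wells either (adjusted p = 0.147). No member of either list passed, also when adjusted over the list alone.

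The other 15 lists did not pass over all nuclei. Hair cell synapse genes had a median log2 change of -0.12 (camera adjusted p = 0.356), supporting cell identity genes -0.04 (0.652) and tectorial matrix genes -0.04 with a mean of 0.09 and a higher direction (0.540), with Tecta at 40.3 CPM against 15.8 ± 10.6 CPM. Notch, Wnt, FGF and TGF-beta and BMP genes had camera adjusted p-values of 0.716, 0.436, 0.891 and 0.716, and FGF genes a median of 0.05 with a mean of -0.03 and a lower direction. Immediate early, antioxidant and nuclear oxidative phosphorylation genes had medians of 0.20, 0.09 and 0.08 (camera adjusted p = 0.0856, 0.0884 and 0.0795). For p53 and apoptosis, the unfolded protein response, cell cycle and adhesion the adjusted p-values were 0.716, 0.339, 0.794 and 0.356, and cell cycle genes had a median of 0.02 with a mean of -0.39 and a lower direction. No member of these 14 lists passed over all genes or adjusted over the list alone. Inflammation and interferon genes (median -0.27, adjusted p = 0.331) had 0 calls over all genes and 1 adjusted over the list alone, the class I histocompatibility gene H2-D1, which stood at 17.8 CPM against 8.83 ± 0.645 CPM.

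Myelin genes lay lower over all nuclei (median log2 change -0.40, positive in 1 of 16, camera adjusted p = 3.20e-05, and 0.562 with an estimated correlation). Mobp stood at 2.43 CPM, within the range of the controls (21.8, 17.2 and 2.23 CPM). Spiral ganglion neuron genes lay lower too (median -0.21, positive in 3 of 28, camera adjusted p = 3.20e-05, and 0.679 with an estimated correlation), with Mafb at 3.98 CPM against 6.003 ± 1.57 CPM. Spiral ganglion neuron-like nuclei were also a smaller share of the library labelled cKO (1.12% against 1.96% ± 0.522), and the list was not adjusted for it. No member of these lists passed, also when adjusted over the list alone. Mitochondrial genome transcripts lay lower by a median log2 change of -1.25 (9 measured, 0 called over all genes and 7 adjusted over the list alone; adjusted p = 1.03e-14; adjusted p = 0.562 with an estimated correlation). mt-Rnr1 stood at 890 CPM against 2496 ± 950 CPM, and mitochondrial counts were 0.768%, 0.429% and 0.746% of the controls' counts and 0.258% of those of the library labelled cKO. Sex-linked genes differed as well: Uty, on the Y chromosome, stood at 3.49 to 4.87 CPM per well in the library labelled cKO against 26.96 to 135 CPM in control wells, and Xist at 601 to 632 CPM against 165 to 554 CPM. The controls differed from one another too. Uty ran from 121 to 135 CPM in control 1, 26.96 to 36.6 CPM in control 2 and 38.5 to 50.7 CPM in control 3. Xist ran from 165 to 216, 534 to 554 and 350 to 501 CPM in the same order. The spread between controls behind the p-values therefore holds a difference in sex-linked genes.

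Among the other classes, Schwann or satellite glia-like nuclei showed the most calls. The weight given to the spread of all genes differed between classes (71.9 prior degrees of freedom here), so numbers of calls are not directly comparable. There 24 of 8252 genes passed, 6 higher and 18 lower, with 473 at an unadjusted p under 0.05, 0 by DESeq2 and 14 by limma voom. Of the fixed myelin list (14 measured) 2 fell, over all genes and adjusted over the list alone: Ncmap, a noncompact myelin protein gene, from 113 ± 15.6 CPM to 49.8 CPM (log2 change -1.30, adjusted p = 0.0288), and Mobp, a gene of central oligodendrocyte myelin, from 70.5, 20.4 and 0 CPM in the controls to no count (floor 3.74 CPM). As a list, myelin genes lay lower (median -0.37, adjusted p = 3.56e-05; adjusted p = 0.844 with an estimated correlation). Matn2 fell from 42.3 ± 4.24 CPM to 4.98 CPM (log2 change -3.15), Edil3 from 125 ± 31.9 CPM to 41.1 CPM and Lrp1b from 126 ± 73.7 CPM to 26.2 CPM (adjusted p = 0.00206, 0.00206 and 0.000470). Insig1, a regulator of cholesterol synthesis, rose from 13.8 ± 1.61 CPM to 56.1 CPM (log2 change 1.92, adjusted p = 0.0219), and Slc4a10 from 73.4 ± 3.23 CPM to 173 CPM (1.13). Itgav also passed as lower, but its control values were 92.6, 1843 and 75.1 CPM against 106 CPM, 1 control standing apart. St18 passed as lower too, with 63.9, 102 and 6.98 CPM in the controls against 1.25 CPM, under the floor. Among the controls Mobp, St18, Lrp1b and Edil3 were lowest in control 3, while Matn2 and Ncmap were highest there. Whether RNA of other cell types added to these differences was not tested. Among the nuclei of this cluster above the background of their pair of wells, 43 genes passed, 23 of them among the 24. When nuclei above that background were clustered anew, 1 gene passed in this class (318 at an unadjusted p under 0.05).

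In spindle or root cell-like nuclei 10 of 4613 genes passed. Of these 6 were mitochondrial genome transcripts that fell. Among them mt-Rnr1 stood at 566 CPM against 3787, 1128 and 8629 CPM in the controls (4514 ± 3803 CPM), a spread of its own that had no weight in the test. Kcnq3 fell from 94.2 ± 13.6 CPM to 14.8 CPM (log2 change -2.70, adjusted p = 0.0216). Wfdc18 rose from 98.0 ± 24.5 CPM to 259 CPM (1.36). In strial marginal cell-like nuclei Pacsin1 rose from 20.98 ± 10.5 CPM to 84.8 CPM (log2 change 2.00, adjusted p = 0.0351), with Gtdc1 and 1 Y-linked gene as the other calls. Lctl was called higher in strial marginal cell-like nuclei above the background of their wells, clustered anew (140 CPM against 47.4 ± 18.7 CPM). Fibrocyte-like nuclei had 3 calls (Zfp335os, Gtdc1 and a Gm gene) and Reissner membrane-like nuclei 1, the Y-linked Uty. Most fibrocyte-like nuclei, the 3576 of cluster 3, were close to the background, with a median of 1.05 times the median UMIs of their pair of wells. None of the calls in fibrocyte-like nuclei was kept among nuclei above that background, in the same clusters or clustered anew. Endothelial, spiral ganglion neuron-like and strial intermediate cell-like nuclei had 0 calls by edgeR, DESeq2 and limma voom, with 282, 433 and 238 genes at an unadjusted p under 0.05.

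Classes made up smaller shares of the library labelled cKO than of the controls in 7 of 10 cases, and no class exceeded the control range. Over all barcodes the direction was the opposite, with 1 of 10 classes below the control range and 5 above it. Hair cell-like nuclei were 0.0642% (0.0308 to 0.118%) of nuclei against 0.222% ± 0.0240 in controls, supporting cell-like nuclei 1.49% (1.30 to 1.69%) against 2.63% ± 1.03, and spiral ganglion neuron-like nuclei 1.12% against 1.96% ± 0.522. Endothelial, spindle or root, strial intermediate and Reissner membrane-like nuclei also lay below the controls. Unnamed nuclei, most of them close to the background of their wells, made up 73.0% against 66.5% ± 3.65. The fibrocyte-like nuclei of cluster 3 were close to that background too. Among nuclei above that background, supporting cell-like nuclei were 4.205% against 4.32% ± 1.63, within the control range, Reissner membrane-like (10.2% against 8.57% ± 0.586) and strial marginal cell-like nuclei (12.8% against 10.04% ± 2.95) lay above it, and hair cell-like nuclei (0.657%, 0.368 to 1.08%, against 0.975% ± 0.117) lay below it. In all 6 of 12 classes lay below and 2 above there, with Schwann or satellite glia-like (3.64% against 5.91% ± 1.77), endothelial (2.19% against 3.59% ± 0.584), spindle or root, macrophage-like and pericyte or smooth muscle-like nuclei also below. With 1 sample against 3 the smallest p an exact permutation test can give is 0.25, so none was run. The ratio of hair cell-like shares turned from 0.289 to 3.27 at resolution 2.0, 1.46 at resolution 0.5, 1.39 with doublets kept and 1.70 over all barcodes.

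**Figure D3:**
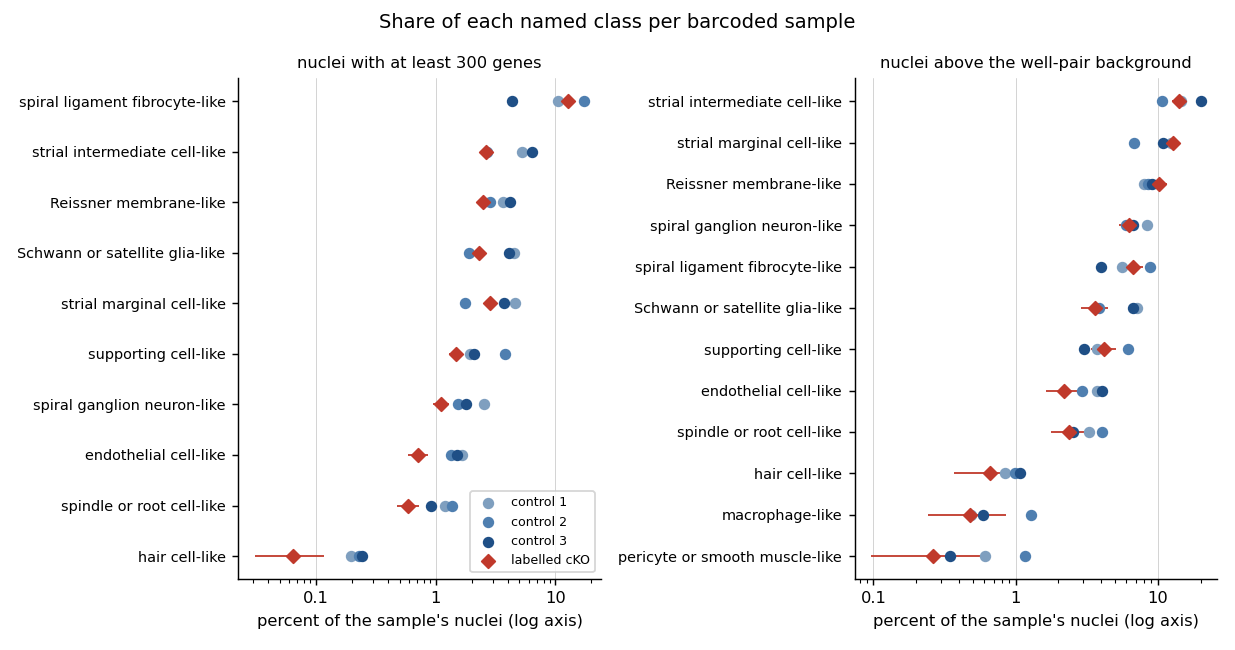
Share of nuclei in each named class (x axis, percent, log scale) for the 3 controls (circles) and the library labelled cKO (diamond, with exact 95% binomial interval), for nuclei with at least 300 genes (left) and for those above the background of their pair of wells (right). Supporting cell-like nuclei lie below the controls on the left (1.49%) and among them on the right (4.205%).

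In wild-type cochleae, SIX1 peaks met H3K27ac peaks and genes more often than random placements did, though most lay outside H3K27ac peaks. The placements were uniform between the first and last gene of a chromosome and took no account of open chromatin or of where reads can be mapped. Of 5521 SIX1 peaks (median width 178 bp), 743 or 13.5% (12.6 to 14.4%) overlapped 1 of the 18882 H3K27ac peaks (median width 526.5 bp), against 0.916% ± 0.1096 over 100 random placements, a 14.7-fold difference with no placement as high. SIX1 peaks lay within 1 kb of either end of a protein-coding gene in 15.3% of cases against 3.42% ± 0.258, and inside a gene span in 58.7% against 40.7% ± 0.638. At the Six1 locus itself (chromosome 12, 73041827 to 73046712), a SIX1 peak of 529 bp lay 3177 bp away, at 73049889 to 73050417. A peak of 302 bp lay inside Eya1, which encodes a SIX1 cofactor (chromosome 1, 14244990 to 14245291), and 1 of 149 bp lay 907 bp from Fgfr3 (chromosome 5, 33737975 to 33738123). The nearest peak to Gjb2 and to Gjb6, which encodes connexin 30, was the same (chromosome 14, 57084313 to 57084476), 14126 and 38825 bp away. Slc26a5 (71783 bp), Gata3 (254910 bp), Pou4f3 (579793 bp), Sox2 (655714 bp) and Atoh1 (1118616 bp) had none near. None of these nearest peaks overlapped an H3K27ac peak. Each list is 1 list of coordinates, so these comparisons are of the lists.

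**Figure D4:**
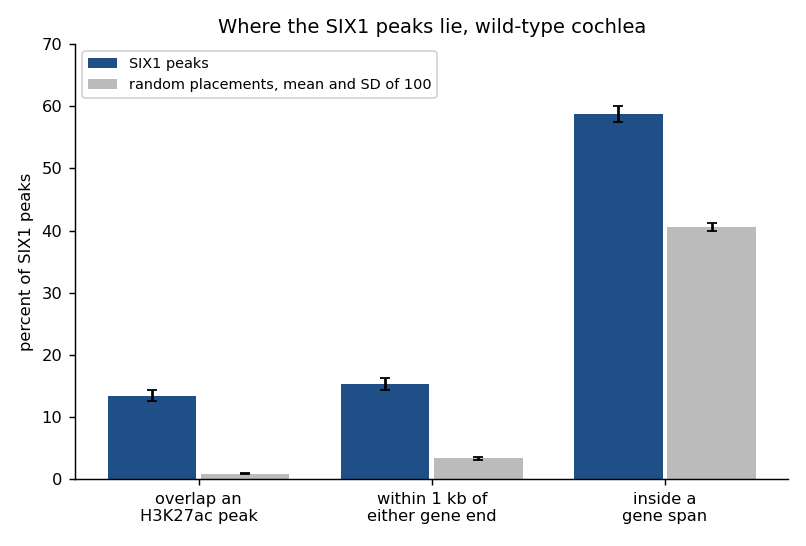
Percent of the 5521 SIX1 peaks (y axis, from 0) that overlap an H3K27ac peak, lie within 1 kb of either end of a protein-coding gene or lie inside a gene span (dark bars, exact 95% binomial intervals), beside the mean and SD of 100 random placements (grey bars). The overlap with H3K27ac is 13.5% against 0.916%.

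Genes with a SIX1 peak within 5 kb of their span had changes close to those of other genes in the library labelled cKO. In supporting cell-like nuclei 2267 of 8248 placed genes had such a peak, and their median log2 change was -0.02, as was that of the genes without a peak. Of the called genes with a place 2 had a peak (Nrxn3 and Lctl) and 9 had none. Over all nuclei the 3167 genes with a peak had a median of -0.0012 against -0.013 for the others, and the 1 called gene, Zfp335os, had no peak. A permutation test with 10000 random sets of genes of like length put the median in supporting cell-like nuclei at percentile 3.95 of the sets (2-sided permutation p = 0.0790). Over all nuclei it lay at percentile 98.94 (2-sided permutation p = 0.0222), a shift of under 0.01 on the log2 scale from the sets' mean of -0.0097. Hair cell-like nuclei were not tested.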

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

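All tests here except that of axonemal genes were chosen after the result was seen, and the axonemal genes were listed before their values were computed but after cilium genes had been seen among the leading genes of cluster 21. 6 of 17080 genes had a log2 change in supporting cell-like nuclei that differed from that in other nuclei by edgeR (645 at an unadjusted p under 0.05). The differences were 1.13 for Klhl14, 0.93 for Nrxn3, 1.62 for Sh3gl3, 0.88 for Kcnb2, 1.12 for Tafa1 and 1.26 for D430041D05Rik. The changes in supporting cell-like nuclei depended on single clusters or wells. Without cluster 23, which held 33 nuclei of the library labelled cKO against 9, 21 and 1, the log2 changes were -0.01 for D430041D05Rik and -0.35 for Tafa1. Those of Kcnb2, Klhl14 and Nrxn3 were -0.10, -0.17 and 0.66 without cluster 20, and that of Sh3gl3 0.35 without well 2 of the library labelled cKO. Among barcodes with under 200 genes, which are not nuclei, the library labelled cKO held Zfp335os at 343 CPM, Gtdc1 at 577 CPM and Lztfl1 at 386 CPM. The highest control values there were 10.3, 136 and 23.1 CPM. Cluster 5, with Otog, Tectb, Xirp2 and Loxhd1 among its leading genes, made up 7.22% of nuclei of the library labelled cKO, and cluster 21, with Xirp2, Ptprq and Ush2a, 0.898%. The nuclei of cluster 5 were close to the background of their wells (median 1.08 times the median of their pair).

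Zfp335os and Lztfl1 were raised in well 1 of the library labelled cKO and Gtdc1 in well 2, so that 3 of 9 combinations of gene and well were over 1.5 times the highest control well. That count restates how the genes were noticed and by itself decides nothing about RNA in 1 well of the first barcoding round. In its raised well each gene had counts in all 96 second-round wells, with at most 4.74% of them in 1 (Gtdc1). Of 19 genes at least 3 times as high in 1 well as in the next, 7 were highest in the library labelled cKO and the others in controls. RNA in 1 well was not tested further and stays open. Expression in nuclei would put each gene, in its own raised well, in barcodes with many genes, but the highest ratio of barcodes with at least 1000 genes to those under 200 genes was 0.284, that of Gtdc1 in well 2. The ratios of Zfp335os and Lztfl1 in well 1 were 0.1098 and 0.135. These values argue against a response of nuclei as the main source of the counts.

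Cluster 21 could be RNA of few nuclei spread over 1 pair of wells, since 66.4% of its nuclei in the library labelled cKO (93 of 140) shared 1 pair. Vestibular hair cells, which bear a kinocilium, fit as well: axonemal genes were higher than in the hair cell-like cluster 24 by a median log2 ratio of 2.92 (1.87 to 3.96; 14 of 15 measured genes), with Hydin at 523 CPM against 18.9 CPM. Of 4 vestibular hair cell genes 3 were higher, Tmc2 and Anxa4 among them, and Calb2 was lower. Nuclei above the background of their wells, clustered anew, held a cluster with the same 15 leading genes but not the same nuclei (29, 25 and 2 in the controls, 41 in the library labelled cKO), whose share in the library labelled cKO was 1.02 times (0.620 to 1.71) that of the highest control and 1.76 times (1.15 to 2.68) that of the controls together. More such cells with the deletion can therefore be neither shown nor excluded.

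Another mix of supporting cell-like clusters is unlikely to be all that raised Nrxn3, which passed within cluster 20 (log2 change 1.98, adjusted p = 0.0142). Within their own cluster Klhl14 changed by 1.39 (SE 0.38, adjusted p = 0.776), Cpne8 by 1.72 (SE 0.33, 0.164) and Lctl by 1.19 (SE 0.39, 0.454), the lowest of the 4 genes. These changes were close to or above those in the class (1.26, 1.16 and 1.33). The 3 genes did not pass there, and Klhl14 is a leading gene of its cluster. For Tecta, with 90.4% of its counts in cluster 23, the change within that cluster was 1.03 (SE 1.15), which leaves the mix open. Single nuclei held at most 13.4% of the counts of those 4 genes in the library labelled cKO, but 1 nucleus held 36.0% of those of Tecta and 1 held 56% of those of Nox3. Of 12 combinations of those 4 genes and a well, 9 lay above every control well, which the deletion of Six1 could bring about, as could any other difference of this 1 library, such as sex.

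With 4 samples, any split into 1 against 3 has a share of at least 0.25. In supporting cell-like nuclei 1 of 4 splits called as many genes as the real one (13, against at most 11 for another sample set apart). Over all nuclei 2 of 4 did (1, against at most 4 for another), so the number of calls may reflect any sample that stands apart.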

How the results depend on the processing

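Each result was recomputed under alternatives, of which 60 left it the same by size, 43 moved it and 3 turned the sign of a log2 change or a direction in camera. Counts and shares were compared by size alone, so the turned shares given further on are not among these 3. The cause was not tested for any of them. No paired analysis was possible because only 1 sample was labelled cKO and its label ties it to no control.

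Nrxn3, Tecta and the other called genes of supporting cell-like nuclei numbered 13. DESeq2 called 4, and another filter on low counts, which kept 9179 genes against 8386, gave 4. All barcodes gave 4, resolution 2.0 gave 2 and 500 genes per nucleus gave 0 (182 at an unadjusted p under 0.05). Leaving out 1 control at a time gave 22 to 40. Among alternatives chosen after seeing the data, a robust dispersion gave 25, 1000 UMIs per nucleus 7, nuclei above the background of their pair of wells clustered anew 0 (215 at an unadjusted p under 0.05), the nuclei of the same clusters above that background 19 (11 of them among the 13), the library without its well 2 gave 5 and the class without cluster 13 gave 4.

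Over all nuclei 1 gene, Zfp335os, was called. DESeq2 called 7, no filter on low counts gave 200, all barcodes 4 and 500 genes per nucleus 0 (509 at an unadjusted p under 0.05). Leaving out 1 control at a time gave 5 to 90. Among alternatives chosen after seeing the data, a robust dispersion gave 4, 1000 UMIs per nucleus 0 (533 at an unadjusted p under 0.05), nuclei above the background 0 (495) and the library without its wells 1, 2 and 3 gave 0 (642), 2 and 3.

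Six1 over all nuclei had a log2 change of 0.02, and between -0.14 and 0.12 with 1 control left out, the lowest without control 1. The gene lists that passed in supporting cell-like nuclei numbered 2, which became 0 with an estimated correlation and 1 to 2 with 1 control left out. The list lost without control 2 or 3 was that of gap junction genes (camera adjusted p = 0.596 and 0.174). Above the background, clustered anew, it did not pass either (0.781), while tectorial matrix genes did (0.0129). Over all nuclei 7 lists passed, 0 with an estimated correlation and 6 to 9 with 1 control left out. Without control 3 the lists of PAX-SIX-EYA-DACH genes (0.156) and hair cell transcription factors (0.236) were lost, and tectorial matrix genes passed (0.0361).

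Genes with a SIX1 peak had a lower direction in camera in supporting cell-like nuclei. The direction turned at a distance of 1 kb (camera value 0.9497) and in nuclei above the background (0.495), and none of these passed. The overlap of SIX1 with H3K27ac peaks was 13.5%, against 9.58% when 50% of a peak had to overlap and 18.2% for peaks wider than the median. The share within 1 kb of either end of a gene was 15.3%, against 27.98% within 5 kb and 18.6% for peaks wider than the median. All 3 of these were chosen after seeing the data, since no strand was given.

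Of 10 classes 7 had shares below the control range and 0 above it, against 1 below and 5 above over all barcodes. In the other settings 5 to 9 classes lay below and 0 to 2 above, with 6 below and 2 above of 12 for nuclei above the background. The share of hair cell-like nuclei relative to the control mean was 0.289, and it turned to 1.70 over all barcodes, 1.46 at resolution 0.5, 3.27 at resolution 2.0 and 1.39 with doublets kept. It was 0.401 at 500 genes. That of supporting cell-like nuclei was 0.567, and it turned to 1.45 over all barcodes and was 0.974 above the background.

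Alternatives were not run for gene tests in hair cell-like nuclei, which were not tested since 3 of the 4 samples held under 20 of them, nor for start sites and the SIX1 motif, since no strand and no genome sequence was used here.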

Other observations

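Zbtb20 had the most SIX1 peaks within 5 kb of its span, 12, followed by Ebf1 with 11, Trpm3 with 10, Rora with 9 and Arid5b with 8. These genes are long (from 187 kb for Arid5b to 858 kb for Trpm3), and length was not adjusted for here. Among the fixed lists, adhesion and junction genes had a SIX1 peak within 5 kb in 13 of 23 cases against a mean of 6.32 in random sets of like length, with Cdh1, Ocln, Tjp1 and Cldn14 among them (permutation test, adjusted p = 0.0798). FGF genes had 10 of 18, with Fgfr1, Fgfr2, Fgfr3 and Etv4 (permutation test, adjusted p = 0.0945), and tectorial matrix genes 8 of 17, with Tectb, Ceacam16 and Otoa (permutation test, adjusted p = 0.190). PAX-SIX-EYA-DACH genes had 7 of 15, Six1, Six2, Six4, Six5, Eya1, Eya4 and Sobp (permutation test, adjusted p = 0.473), and nuclear oxidative phosphorylation genes 1 of 35, Cox8a (permutation test, adjusted p = 0.206). No list passed.

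Mitochondrial genome transcripts lay lower in all 10 comparisons of the library labelled cKO, with list medians from -2.61 to -0.42 on the log2 scale. H3K27ac peaks lay within 1 kb of either end of a protein-coding gene in 31.9% of cases, against 4.53% ± 0.147 in random placements. In Schwann or satellite glia-like nuclei Zbtb16, which holds SIX1 peaks, fell from 679 ± 240 CPM to 319 CPM (log2 change -1.21, adjusted p = 0.0288), Tacc1 fell from 480 ± 95.9 CPM to 215 CPM (-1.26, adjusted p = 0.0132) and Nudt4 rose from 113 ± 24.1 CPM to 242 CPM (1.02, adjusted p = 0.0288). Itgav and Ggact were carried by 1 well of control 2 (991 and 779 CPM), with 91.6% and 90.4% of their counts there in 1 second-round well.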
